A study of Mus musculus with 6 samples.

How the data were processed

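RNA was sequenced from mouse epiblast-like cells (EpiLCs) of the C57BL/6 strain, 3 libraries labelled wild type (WT) and 3 labelled Cables2 deficient (KO). Per the labels' protocols, ESCs were grown with LIF, CHIR99021 and PD0325901 and were moved to fibronectin-coated plates in medium with activin A (20 ng/mL), basic FGF (12 ng/mL) and KSR (1%), and total RNA was taken on day 2. Libraries were made from 500 ng of RNA after ribosomal RNA depletion with a directional kit and were sequenced in paired ends of 36 bases on a NextSeq 500, also per the labels' protocols. The authors deposited 1 table of 49585 gene rows with the whole-number read counts of each gene in each library, not normalized, as the values and the file headers show. The p-values and their FDR correction in that table come from the authors' own test of WT against KO, per the file headers, and the signed fold of the same test is negative where KO is lower. The genome build mm10 and edgeR are named in the submitters' processing notes, without versions. The aligner, the counting program, its strand and multiple-mapping settings and the annotation release are not given in the sources used here. For this reason genes that overlap, lie antisense to each other or share sequence with paralogs or pseudogenes carry an uncertainty that the counts cannot show. Another 18 columns of values per library (normalized and related values) were not used.

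Count columns carry the genotype and a library number from 01 to 06, so each was assigned to its group by name. The replicate numbers of the labels do not appear in the columns, and libraries are named here by group and library number. The symbols of 95.1% of the rows were found in GENCODE M21 (GRCm38, the reference for mm10), and 91.1% of those had identical coordinates after 1 was added to the start. Coordinates in the text are those of the table, counted from 1, and gene identifiers, strands and biotypes come from GENCODE M21.

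Totals per library ran from 4234788 to 5206717 counts, and 17987 genes had a count in at least 1 library. A count of 3, used as a floor, corresponds to 0.576 to 0.708 CPM (counts scaled to library size). Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. Protein-coding genes held 88.3% to 90.1% of the counts. The mitochondrial ribosomal RNA genes and the abundant small RNA genes Rn7sk, Rmrp, Rpph1 and Terc were listed at 0 in all libraries. Pairs of libraries within a group differed by more than counting noise (chi-square over degrees of freedom 1.75 to 2.73), and pairs between groups by more (4.69 to 6.99). This does not show whether the libraries of a group came from separate cultures, and the model takes each library as 1 sample, per the labels.

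Genes were filtered with filterByExpr with the groups, which left 11594. Counts were scaled with TMM factors (0.987 to 1.02) and fitted with edgeR's robust quasi-likelihood model with the group as the only term. Changes are KO minus WT on the log2 scale, p-values were adjusted by Benjamini-Hochberg over all tested genes, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. The common biological coefficient of variation was 5.03%. Group means are given as CPM ± SD over 3 libraries. Gene lists with at least 5 measured members were tested against all other genes with camera (limma) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 26 lists tested. Each list is also given as the number of members called over all genes and when adjusted over the list alone, and camera with an estimated correlation and fry were run beside it. Camera asks whether a list differs from other genes, and fry whether its members moved together in 1 direction, so their p-values answer different questions. Of the 15 lists called with the preset correlation, 0 passed in camera with the estimated correlation, where 4 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0635. For the naive pluripotency list this was not due to a larger correlation, since its estimate of 0.0075 was below the preset value. For each chromosome the share of called genes was compared with all other chromosomes by Fisher's exact test, adjusted over the chromosomes.

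The tests, the lists, the naming rule and most alternatives were chosen before the data were examined. The p53 list was included because published work on this deletion had examined that pathway, so it was not chosen blind to earlier results. The rule names 17 genes whatever their values (Cables2, its paralog and neighbours, and genes of the p53, signalling and pluripotency programmes). It adds the 10 higher and 10 lower called genes with the largest fitted change among those with a mean of at least 1 CPM, KO libraries all on 1 side of the WT libraries, and a symbol that is not a predicted model. From each list it takes up to 4 called members with the smallest adjusted p, or the member with the smallest p if none was called. Some genes that the rule selects are not reported here. The lists cover neighbours of Cables2, p53 targets, small-subunit and large-subunit ribosomal proteins, core, naive, and formative and primed pluripotency, and primitive streak and mesendoderm. They also cover Nodal and activin, Wnt, BMP, and FGF and ERK targets, the integrated stress response, G1/S and DNA replication, G2/M, the Cables family and reported partners, glycolysis and hypoxia, and cholesterol synthesis. The remaining lists are neuroectoderm, extraembryonic endoderm, trophoblast, fibroblast, 2-cell-like, germline, imprinted, Y-linked, mitochondrially encoded, and immediate-early and heat shock genes. Symbols that the table writes differently were matched through listed gene synonyms where only 1 candidate was found, and 1 gene of the 2-cell-like list was not found.

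The alternatives were RLE size factors, upper-quartile factors and library size alone in place of TMM, no low-count filter, a filter of CPM of at least 1 in 3 libraries, protein-coding genes alone, DESeq2's Wald test, limma-voom, an adjusted p under 0.01, a change of at least 2-fold, and leaving out each library in turn. The fits without the genes of chromosomes 6 and 8, without the ribosomal RNA rows Gm26917 and Rn18s-rs5, and with a trend on GC content and exon length removed were added after seeing the data. GC content and exon length are those of the longest annotated transcript in the reference and were available for 97.9% of the tested genes.

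The edgeR fit was tested on counts simulated from the real means, library sizes and dispersions of the KO and WT comparison, with 200 genes changed. The low-count filter then left 11497 genes, and recovery was taken over the changed genes among them. The fit recovered 44.4% of the genes changed 1.3-fold and 86.6% of those changed 2-fold. It made 13 false calls (9.2% of the calls), a share above the adjusted p threshold of 0.05. The camera list test called a simulated list of 37 shifted genes as higher, and 6 of 200 random lists had a p under 0.05. Genes were drawn independently in these simulations, so they do not show how the list test behaves with correlated members. In the real data the estimated correlation reached 0.432, for the mitochondrially encoded list. The work used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.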

Results

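RNA sequencing libraries were made from mouse epiblast-like cells (EpiLCs), a culture model of the early postimplantation epiblast that is obtained by moving embryonic stem cells (ESCs) from LIF and kinase inhibitors to activin A and basic FGF. The cells were of the C57BL/6 strain and were collected on day 2 of induction. The series compared 3 wild-type (WT) libraries with 3 libraries of cells lacking Cables2, hereafter knockout (KO), a gene for a cyclin-dependent kinase binding protein of the Cables family. The WT libraries held 4848967, 4477305 and 4234788 counts and the KO libraries 5134417, 5206717 and 4442618. The single row Gm26917, a gene model that takes ribosomal RNA reads, held between 8.34% and 10.2% of the counts of a library. Mitochondrially encoded transcripts made up 0.141% to 0.152% of the counts in WT and 0.204% to 0.243% in KO, so that the libraries of the groups did not overlap in this share. It leaves out most reads of mt-Co2, mt-Co3 and mt-Atp6, which are usually abundant and were listed with only 2 to 11 counts in each library, so it is not the full mitochondrial content. The labels do not say whether the libraries of a group came from separate cultures or ESC lines, so the p-values measure only the spread between these libraries, which may be technical.

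The first question was whether the targeted transcript was lost in every KO library. Cables2 (ENSMUSG00000038990.14, chromosome 2, 180258540 to 180273496, minus strand, mm10) had 114, 111 and 121 counts in WT libraries 01, 02 and 03 and 6, 11 and 4 counts in KO libraries 04, 05 and 06. This corresponded to 23.9, 24.8 and 28.9 CPM (counts scaled to library size) in WT and 1.17, 2.09 and 0.904 CPM in KO, with means of 25.8 ± 2.65 and 1.39 ± 0.621 CPM (SD, n = 3 each). The KO level was 5.58% of WT, a log2 fold change of -4.16 ± 0.26 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.5e-23). The authors' deposited table gives Cables2 a signed fold of -17.9. Every library therefore carried the Cables2 level of its genotype label. The paralog Cables1 had a log2 fold change of -0.19 ± 0.19 and did not pass the test (adjusted p = 0.547). Its value was -0.09 without WT library 01, -0.33 without WT library 02, -0.34 without KO library 05 and -0.04 without KO library 06.

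Rps21, which encodes a protein of the small ribosomal subunit, was lower in every KO library. It lies on the opposite strand of chromosome 2 (ENSMUSG00000039001.12, 180257377 to 180258445, plus strand), and its annotated end is separated from that of Cables2 by 94 bases. Rps21 had 1880, 1779 and 1680 counts in WT and 873, 901 and 748 counts in KO, or 397 ± 3.49 CPM against 170.0 ± 0.942 CPM (SD, n = 3 each). Its KO level was 42.8% of WT (log2 fold change -1.22 ± 0.05, adjusted p = 2.17e-32), and the authors' deposited table gives a signed fold of -2.34. On the same side of Cables2, Lama5, a laminin chain gene, had a log2 fold change of 0.02 ± 0.05 (adjusted p = 0.811), and Adrm1, a proteasome ubiquitin receptor gene, one of 0.01 ± 0.08 (adjusted p = 0.957). Rbbp8nl had a log2 fold change of 0.03 ± 0.25 (adjusted p = 0.961). Of the 21 genes listed as neighbours of Cables2, 18 were measured, 1 rose and 2 fell, and the same numbers passed when adjusted over the list alone. The number that rose was 2 without WT library 02 or 03 or KO library 04 or 05. Besides Rps21, the transcription factor gene Tcfl5 fell (-0.45 ± 0.07, adjusted p = 7.89e-07) and the chromatin reader gene Dido1 rose (0.44 ± 0.07, adjusted p = 6.25e-07). The list as a whole did not pass the test against other genes (camera adjusted p = 0.997 in the upward direction). Its median log2 fold change was 0.02 and its mean -0.03, so these differed in sign. The median was 0.0012 without KO library 05, 0.01 without WT library 03, 0.04 without WT library 01 and 0.05 without WT library 02 or KO library 06.

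**Figure D1:**
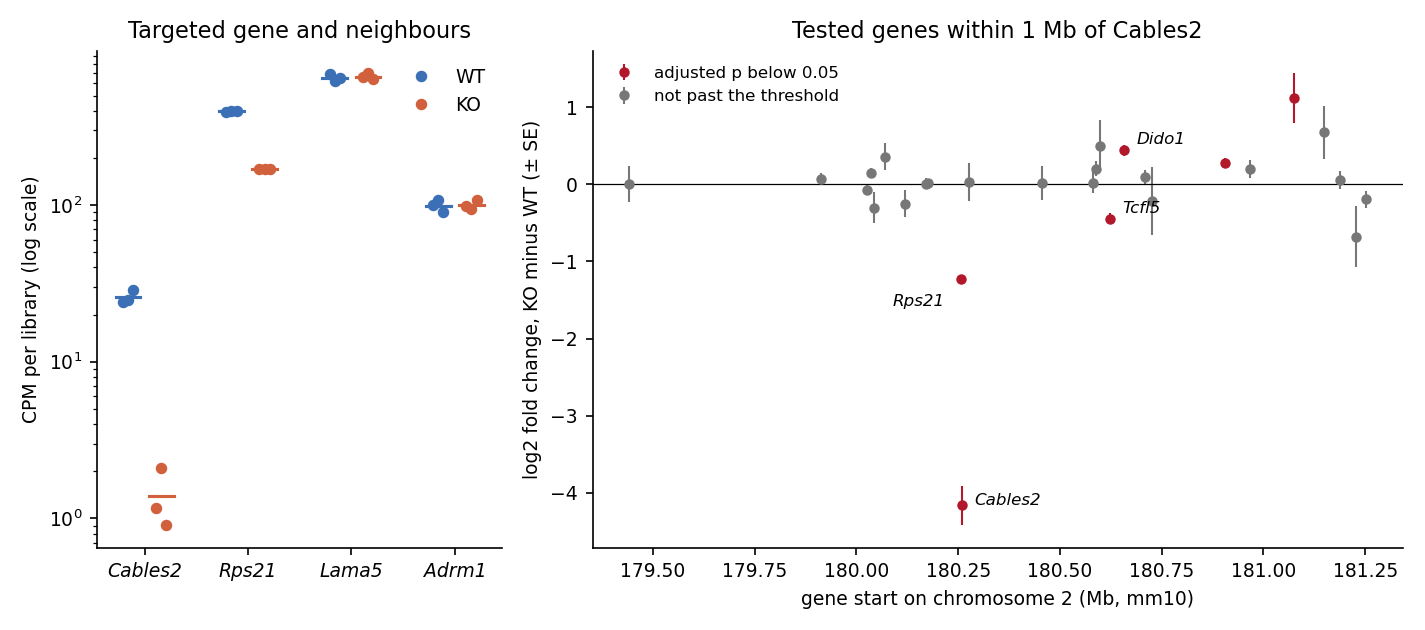
Left, CPM per library on a log scale for Cables2, Rps21, Lama5 and Adrm1 in 3 WT and 3 KO libraries, with horizontal lines at the group means. Right, log2 fold change (KO minus WT, bars are SE) of the tested genes within 1 Mb against gene start on chromosome 2, where Cables2 at -4.16 and Rps21 at -1.22 stand below the other 25 genes, whose median was 0.03.

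The second question was which transcripts differed between the genotypes. In the KO, 943 of 11594 tested genes rose and 1059 fell at an adjusted p under 0.05, together 17.3% of the genes. Most of the changes were small, with a median size of 0.39 on the log2 scale. At least 2-fold changes were fitted for 105 of the genes that rose and 44 of those that fell. In 1854 of the called genes (92.6%) the 3 KO libraries lay on 1 side of the 3 WT libraries. Among all tested genes this share was 31.6%, against 10% by chance for 3 libraries against 3. Among called genes, 47.1% were higher in KO, and this share was 53.2% with upper-quartile factors and 53.4% with library size alone. The authors' deposited table calls 1574 genes at the same threshold, 721 higher and 853 lower. Of these, 1525 were called here too, all with the same sign.

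By the naming rule, the genes with the largest rise included Vgf, which encodes a secreted neuropeptide precursor, at 8.99 ± 0.473 CPM in WT and 38.2 ± 4.61 CPM in KO (SD, n = 3 each; log2 fold change 2.08 ± 0.16, adjusted p = 1.31e-18). Fam212b rose by 2.08 ± 0.29 (adjusted p = 1.9e-08), the anoctamin gene Ano3 by 2.00 ± 0.23 (adjusted p = 8.32e-11) and the proneural transcription factor gene Neurod1 by 1.94 ± 0.40 (adjusted p = 0.000128) on the log2 scale. The corneal keratin gene Krt12 rose by 2.03 ± 0.50, from a WT mean of 0.83 CPM that lies near the floor. Cpz (1.89), Chst1 (1.78), Slc5a1 (1.77), Mfap2 (1.72) and Neb (1.70) completed the 10 largest rises in log2 fold change. The largest fall after Cables2 was that of Ndnf, a neuron-derived secreted factor gene on chromosome 6, with 39, 19 and 19 counts in WT and 1, 1 and 5 in KO (-3.52 ± 0.51, adjusted p = 7.81e-08). Its KO mean of 0.505 CPM was below the value of 3 counts in each library, so that the size of the fold is uncertain. The transcription factor gene Ebf1 fell (-1.87 ± 0.31, adjusted p = 2.21e-06), as did the cytochrome oxidase subunit gene Cox7a1 (-2.14 ± 0.53, adjusted p = 0.00195) and the mitochondrial transport gene Mgarp (-1.95 ± 0.51, adjusted p = 0.00293). Cox7a1 had only 2, 6 and 2 counts in KO and Mgarp 4, 6 and 2, so the sizes of both folds are uncertain. Leaving out 1 library moved Cox7a1 to as low as -2.79. Adamts15 (-1.67) and the noncoding RNA gene Halr1 on chromosome 6 (-1.54) fell too, and the pluripotency genes Nanog and Nr0b1 were also among the 10 largest falls. The call of Adamts15 ended without WT library 01 (adjusted p = 0.0527).

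Targets of the transcription factor p53 rose together in the KO. Of 37 measured members of the list, 23 rose and 1 fell, or 24 and 2 when adjusted over the list alone, with a median log2 fold change of 0.46. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, went from 52.8 ± 5.05 CPM to 137 ± 3.55 CPM (SD, n = 3 each; 1.37 ± 0.08, adjusted p = 4.97e-25). Mdm2, the ubiquitin ligase that degrades p53, rose by 0.84 ± 0.06 (adjusted p = 2.1e-18), the cyclin gene Ccng1 by 0.96 ± 0.06 (adjusted p = 2.29e-24) and the polo-like kinase gene Plk2 by 1.28 ± 0.09 (adjusted p = 1.08e-19). The only member that fell was Sesn1, a stress-inducible metabolic regulator (-0.47 ± 0.14, adjusted p = 0.0107), named here after its value was seen because the count was 1. The number that fell was 0 without WT library 03 and 2 without KO library 06. The list test gave an adjusted p of 8.17e-10 against all other genes, and adjusted p = 0.0635 with an estimated correlation. Trp53 itself was 0.16 ± 0.06 higher (adjusted p = 0.0404), a call that ended in each of the 6 fits that left out 1 library, with adjusted p between 0.0506 and 0.198. The same libraries also differed in the mitochondrial share of counts, which was at most 0.152% in WT and at least 0.204% in KO. A link between this share and the p53 targets was not tested.

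Genes of naive pluripotency, which are switched off as ESCs become EpiLCs, fell in the KO. Of 18 measured members, 12 fell and 1 rose, with the same numbers adjusted over the list alone and a median log2 fold change of -0.62. Nanog, a homeobox gene of the pluripotency network on chromosome 6, went from 67.4 ± 2.62 CPM to 21.1 ± 2.94 CPM (SD, n = 3 each; -1.68 ± 0.11, adjusted p = 3.74e-21). The orphan nuclear receptor genes Nr0b1 (-1.60 ± 0.16, adjusted p = 9.39e-13) and Esrrb (-0.84 ± 0.08, adjusted p = 7.27e-14) and the DNA demethylase gene Tet2 (-0.88 ± 0.09, adjusted p = 1.58e-13) fell as well. Klf2 on chromosome 8 was the member that rose (0.61 ± 0.17, adjusted p = 0.00449). None rose without WT library 01. The list test gave an adjusted p of 1.83e-07, and adjusted p = 0.0635 with an estimated correlation. Formative and primed genes, which are gained in EpiLCs, rose on balance: 10 of 21 measured members rose and 3 fell, or 12 and 4 adjusted over the list alone, with a median of 0.25. The POU factor gene Pou3f1 went from 255 ± 19.9 CPM to 469 ± 33.7 CPM (0.88 ± 0.05, adjusted p = 1.5e-23) and the epiblast growth factor gene Fgf5 from 16.5 ± 2.85 CPM to 36.8 ± 5.0 CPM (1.17 ± 0.14, adjusted p = 5.2e-10; SD, n = 3 each). The claudin gene Cldn6 (0.98 ± 0.11, adjusted p = 1.35e-10) and the kinase gene Pim2 (0.74 ± 0.08, adjusted p = 4.25e-11) rose too, whereas Otx2 had a log2 fold change of 0.05 ± 0.10 (adjusted p = 0.798), or 0.02 without WT library 02 or KO library 05. The list test gave an adjusted p of 0.00792, and adjusted p = 0.239 with an estimated correlation. The naive and formative differences go with other differences between the same libraries, among them the mitochondrial share (at most 0.152% in WT and at least 0.204% in KO) and the higher fibroblast list (median 0.44, adjusted p = 0.0191, but 0.187 with an estimated correlation and 0.0719 with a filter of CPM of at least 1 in 3 libraries).

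Core pluripotency genes, shared by ESCs and EpiLCs, did not pass as a list (camera adjusted p = 0.957 in the downward direction, median 0.02, mean 0.0015). Of 14 measured members 2 rose and 4 fell, or 4 and 4 adjusted over the list alone. Pou5f1, which encodes Oct4, had a log2 fold change of 0.07 ± 0.05 (adjusted p = 0.344), or 0.04 without WT library 01 or KO library 05 and 0.11 without WT library 03. The Nodal co-receptor gene Tdgf1 rose (0.36 ± 0.05, adjusted p = 1.1e-08), and the E-cadherin gene Cdh1 on chromosome 8 (-0.23 ± 0.04, adjusted p = 1.17e-05) and the RNA-binding protein gene Lin28a (-0.20 ± 0.05, adjusted p = 0.000536) fell. Sox2 was listed with 0 to 2 counts in each library and was not tested. How reads of overlapping genes were counted is not given, so this does not show that Sox2 was absent. Of the 25 genes of the primitive streak and mesendoderm list, 4 were measured, too few for a list test, and 1 rose and 1 fell, in all tested genes and adjusted over the list alone. Wnt3, a ligand gene needed for streak formation, rose from 2.32 ± 0.741 CPM to 6.04 ± 1.74 CPM (SD, n = 3 each; 1.39 ± 0.35, adjusted p = 0.00205). Cdx1, a caudal homeobox gene, fell (-1.27 ± 0.46, adjusted p = 0.0413), a call that ended in each of the 6 fits without 1 library (adjusted p up to 0.172). T, which encodes brachyury, had 0 to 9 counts in each library, below the filter, and no difference was detectable at this depth.

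Among signalling lists, targets of Nodal and activin, the pathway driven by the EpiLC medium, were higher in the KO. Of 13 measured members 5 rose and 1 fell, with the same numbers adjusted over the list alone and a median of 0.24. Lefty1, a Nodal antagonist and target, went from 45.9 ± 6.46 CPM to 115 ± 13.9 CPM (SD, n = 3 each; 1.33 ± 0.09, adjusted p = 3.74e-21). Nodal itself rose by 0.47 ± 0.07 (adjusted p = 1.47e-07) and Lefty2 by 0.95 ± 0.18 (adjusted p = 3.75e-05). The member that fell was Bambi, a pseudoreceptor of the TGF-beta family (-0.50 ± 0.19, adjusted p = 0.0480). The list test gave an adjusted p of 0.0302, and adjusted p = 0.54 with an estimated correlation. The call of the list ended without WT library 01 (adjusted p = 0.0509, median 0.15), WT library 03 (0.102, median 0.15) or KO library 04 (0.0885, median 0.13), and without the genes of chromosomes 6 and 8 (adjusted p = 0.0534). It also ended with no low-count filter (adjusted p = 0.173, median 0.13) and with a filter of CPM of at least 1 in 3 libraries (0.0874). Bambi did not pass in any of the 6 fits without 1 library (adjusted p up to 0.158).

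Wnt targets were lower, with 1 of 10 measured members up and 5 down, the same numbers adjusted over the list alone and a median of -0.30 (list adjusted p = 0.0277, and adjusted p = 0.198 with an estimated correlation). The call of the list ended with no low-count filter (adjusted p = 0.0955) and with a filter of CPM of at least 1 in 3 libraries (0.0677). Of the Wnt members, 2 fell without WT library 02 and 3 fell without WT library 01 or 03 or KO library 04 or 05, and 0 rose without WT library 01 or 02 or KO library 04. The proto-oncogene Myc fell (-0.42 ± 0.06, adjusted p = 3.46e-07), as did the cyclin gene Ccnd1 (-0.25 ± 0.07, adjusted p = 0.00322), the Wnt effector gene Lef1 (-0.40 ± 0.11, adjusted p = 0.00775) and the Wnt inhibitor gene Nkd1 on chromosome 8 (-0.46 ± 0.15, adjusted p = 0.0243). The call of Lef1 ended without WT library 02 (-0.31, adjusted p = 0.1) or KO library 05 (-0.24, adjusted p = 0.179), and that of Nkd1 without WT library 01, 02 or 03 or KO library 04 (adjusted p up to 0.138). Axin2, a feedback gene of the pathway, had a log2 fold change of -0.28 ± 0.16 (adjusted p = 0.249). BMP targets were lower in a list of only 6 measured members, of which 2 fell and none rose, or 3 and 0 adjusted over the list alone (median -0.41, adjusted p = 0.0277, and adjusted p = 0.239 with an estimated correlation). The inhibitory Smad gene Smad6 fell (-0.51 ± 0.16, adjusted p = 0.0141), a call that ended without WT library 01 (adjusted p = 0.0519) or WT library 02 (0.0582), and Bambi is shared with the Nodal list. The BMP list call ended without WT library 01 (median -0.16, adjusted p = 0.11), KO library 04 (0.0537) or KO library 05 (0.0896). The number of BMP members that fell was 0 without WT library 01 or 02 and 1 without WT library 03 or KO library 04, 05 or 06. Of 16 measured FGF and ERK feedback genes 4 fell and 1 rose, or 5 and 1 adjusted over the list alone (median -0.12, adjusted p = 0.0302, and adjusted p = 0.187 with an estimated correlation). The Ets factor gene Etv4 (-0.48 ± 0.06, adjusted p = 6.68e-10), the ERK phosphatase gene Dusp4 on chromosome 8 (-0.53 ± 0.07, adjusted p = 8.21e-09) and the receptor signalling inhibitor gene Spry4 (-0.34 ± 0.08, adjusted p = 0.00203) fell, and Myc is shared with the Wnt list. The FGF and ERK list call ended without WT library 01 (adjusted p = 0.0509) or KO library 06 (0.0521), and its median was -0.08 without KO library 04. It also ended with no low-count filter (adjusted p = 0.0579, median -0.07) and with the CPM filter (0.0719, median -0.07). The number of its members that rose was 0 without WT library 02 or KO library 06.

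Glycolysis and hypoxia genes were lower in the KO, and none of the 23 measured members rose. The number that fell was 12, also when adjusted over the list alone, with a median of -0.31. Slc2a3, a neuronal-type glucose transporter gene on chromosome 6, went from 509 ± 20.3 CPM to 189 ± 13.3 CPM (SD, n = 3 each; -1.43 ± 0.05, adjusted p = 8e-37). The hexokinase gene Hk2 (-0.63 ± 0.05, adjusted p = 2.05e-17) and the triosephosphate isomerase gene Tpi1 (-0.42 ± 0.05, adjusted p = 6.67e-10) lie on chromosome 6 too, whereas the glucose transporter gene Slc2a1 (-0.68 ± 0.06, adjusted p = 5.22e-15) does not. The list test gave an adjusted p of 1.33e-06, and adjusted p = 0.187 with an estimated correlation. Without the genes of chromosomes 6 and 8 the call was kept (adjusted p = 2.32e-05) and the median was -0.10. The median was -0.20 without WT library 03 and -0.19 without KO library 06.

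Cholesterol synthesis genes fell without exception among the called members, 14 of 22 measured, or 16 adjusted over the list alone, with 0 higher (median -0.22, adjusted p = 2.99e-06, and adjusted p = 0.187 with an estimated correlation). The number that fell was 9 without KO library 05. The sterol oxidase gene Msmo1 on chromosome 8 fell by 0.68 (SE 0.07, adjusted p = 1.3e-13). Srebf2, the transcription factor gene of the sterol response, had a log2 fold change of -0.27 ± 0.05 (adjusted p = 2.36e-06), its regulator Insig1 one of -0.32 ± 0.05 (adjusted p = 4.48e-06) and the lanosterol synthase gene Lss one of -0.35 ± 0.07 (adjusted p = 2.97e-05). Of 22 genes of the integrated stress response, 12 fell and 3 rose, with the same numbers adjusted over the list alone (median -0.19, adjusted p = 0.00278, and adjusted p = 0.135 with an estimated correlation). The one-carbon enzyme gene Mthfd2 (-0.54 ± 0.05, adjusted p = 1.18e-15) and the asparagine synthetase gene Asns (-0.38 ± 0.05, adjusted p = 6.67e-09) lie on chromosome 6. The stress cofactor gene Nupr1 (-0.64 ± 0.09, adjusted p = 1.17e-08) and the amino acid transporter chain gene Slc3a2 (-0.33 ± 0.05, adjusted p = 4.66e-08) lie elsewhere.

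Genes of the G1/S transition and DNA replication were slightly lower. Of 24 G1/S and DNA replication genes 7 fell and 0 rose, or 9 and 0 adjusted over the list alone (median -0.11, adjusted p = 0.00193, and adjusted p = 0.135 with an estimated correlation). The replication licensing genes Cdt1 on chromosome 8 (-0.44 ± 0.06, adjusted p = 2.47e-09), Mcm2 on chromosome 6 (-0.31 ± 0.04, adjusted p = 3.31e-08), Mcm6 (-0.22 ± 0.05, adjusted p = 0.000539) and Mcm5 on chromosome 8 (-0.21 ± 0.05, adjusted p = 0.000619) had the smallest adjusted p. Of the 19 members on other chromosomes, 3 fell. Of 24 G2/M genes 1 rose and 0 fell, in all genes and adjusted over the list alone (median 0.02, adjusted p = 0.816), and 2 rose without WT library 02 or KO library 04. The gene called with all libraries was Cdc20, an activator of the anaphase-promoting complex (0.23 ± 0.05, adjusted p = 0.000338). The list of the Cables family and its reported partners had 2 of 10 measured members up and 1 down, the same adjusted over the list alone (median 0.03, adjusted p = 0.663). In each of the 6 fits without 1 library, 1 member rose, and the median was 0.01 without WT library 01 and 0.02 without KO library 05. The p53 family gene Trp73 rose (0.93 ± 0.14, adjusted p = 3.96e-07) and the kinase gene Abl1 fell (-0.22 ± 0.06, adjusted p = 0.00858), a call that ended without WT library 01 (adjusted p = 0.13) or KO library 04 (0.0587).

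Ribosomal protein genes other than Rps21 differed by small amounts. Of 31 measured small-subunit genes 5 rose and Rps21 fell, in all genes and adjusted over the list alone, with a median of 0.07 (adjusted p = 0.0417, and adjusted p = 0.54 with an estimated correlation). Rps24 rose by 0.22 ± 0.04 (adjusted p = 0.000119), Rps13 by 0.16 ± 0.05 (adjusted p = 0.0231) and Rps19 by 0.13 ± 0.05 (adjusted p = 0.0412). The small-subunit list passed in only 1 of the fits without 1 library, that without KO library 04, and its adjusted p reached 0.182. It also ended with no low-count filter (0.0955), with the CPM filter (0.0719) and without the genes of chromosomes 6 and 8 (0.219). The fry test, which asks whether members moved together in 1 direction and not whether the list differs from other genes, gave an adjusted p of 0.326. Its mixed form, which asks for changes in either direction and includes Rps21, gave an adjusted p of 9.22e-06. The number of members that rose was 9 with upper-quartile factors, 7 with library size alone, 4 with RLE factors, 3 with the CPM filter, 2 with no filter and 1 without chromosomes 6 and 8. It was 3 without WT library 01 or KO library 05 and 1 without WT library 03 or KO library 06. The call of Rps13 ended without WT library 01 or 03 or KO library 04 or 06 (adjusted p up to 0.111), and that of Rps19 without WT library 02 or 03 or KO library 05 or 06 (0.07, adjusted p = 0.357 without the last). Rps12 was listed with 0 to 12 counts in each library and was not tested. Of 47 large-subunit genes 15 rose and 2 fell, or 19 and 2 adjusted over the list alone, with a median of 0.09 (adjusted p = 0.0105, and adjusted p = 0.475 with an estimated correlation). The number that rose was 19 with upper-quartile factors, 9 without chromosomes 6 and 8, 10 without WT library 01 and 8 without KO library 06. Rpl19 rose by 0.28 ± 0.05 (adjusted p = 2.52e-06), Rpl23a by 0.23 ± 0.05 (adjusted p = 0.0013) and Rpl38 by 0.21 ± 0.05 (adjusted p = 0.00152), and Rpl32 on chromosome 6 fell (-0.22 ± 0.04, adjusted p = 3.49e-05). The large-subunit call ended without WT library 01 (adjusted p = 0.0509) or KO library 06 (0.055), and that of Rpl23a with DESeq2 (0.131). Processed pseudogenes share sequence with many ribosomal protein genes, and the authors' treatment of such reads is not given in the sources used here.

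Markers of other cell types that the cultures could hold gave mixed values. The fibroblast list had 3 of 8 measured members up and 0 down, or 4 and 0 adjusted over the list alone (median 0.44, adjusted p = 0.0191, and adjusted p = 0.187 with an estimated correlation). Other genes among its 18 members had too few counts to be tested. Col1a2 had 12, 9 and 3 counts in WT and 8, 7 and 8 in KO, and Lox 0, 1 and 2 against 6, 2 and 4. Pdgfrb had 9, 7 and 9 against 7, 0 and 7, and Postn, Lum and S100a4 had 0 in every library. Tagln, a smooth muscle and fibroblast actin-binding protein gene, went from 11.9 ± 1.96 CPM to 21.9 ± 4.74 CPM (SD, n = 3 each; 0.88 ± 0.18, adjusted p = 7.58e-05). Acta2, which encodes smooth muscle actin, rose from 1.19 ± 0.328 CPM to 3.19 ± 0.448 CPM (1.40 ± 0.46, adjusted p = 0.0262) and the collagen gene Col5a1 by 0.42 ± 0.15 (adjusted p = 0.0430). The call of Acta2 ended without WT library 01 or 03 or KO library 05 or 06 (adjusted p up to 0.103), and that of Col5a1 without WT library 02 or KO library 04 or 05 (up to 0.283). The number of fibroblast members that rose was 1 without KO library 05. The median of the fibroblast list was 0.27 without KO library 04, and its call ended with a filter of CPM of at least 1 in 3 libraries (adjusted p = 0.0719). Extraembryonic endoderm genes did not pass as a list (median -0.25, adjusted p = 0.0638), with 1 of 10 measured members up and 5 down, the same adjusted over the list alone. The basement membrane collagen genes Col4a1 (-0.49 ± 0.08, adjusted p = 3.08e-06) and Col4a2 (-0.68 ± 0.12, adjusted p = 1.32e-05) lie on chromosome 8. The laminin gene Lamb1 rose (0.29 ± 0.05, adjusted p = 6.13e-06), and the matrix protein gene Sparc fell (-0.19 ± 0.06, adjusted p = 0.0203), a call that ended without WT library 01 or 03 or KO library 04 or 06 (adjusted p up to 0.0955). The list passed without WT library 02 or KO library 06, and its median was -0.46 without KO library 05 and -0.47 without KO library 06. The number of its members that fell was 2 without WT library 01 or 03 or KO library 04 and 3 without WT library 02 or KO library 06. It also passed with no low-count filter (adjusted p = 0.0059, median -0.59), the CPM filter (0.0266, median -0.41) and the GC and length trend removed (0.0498). Without the genes of chromosomes 6 and 8 its adjusted p was 0.309, so the result depends on these choices. For a shift in 1 direction, and not against other genes, fry gave an adjusted p of 0.0129.

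The neuroectoderm list had 1 of 7 measured members up and 0 down, or 2 and 0 adjusted over the list alone (adjusted p = 0.856 in the upward direction, although the median was -0.04 and the mean -0.08). The member that rose was Nes, which encodes the intermediate filament nestin (0.46 ± 0.08, adjusted p = 6.52e-06), and 2 rose without WT library 01 or KO library 06. The trophoblast list had 1 of 9 measured members up and 0 down, also adjusted over the list alone (median 0.20, adjusted p = 0.329), and this was the keratin gene Krt18 (0.33 ± 0.09, adjusted p = 0.00377). The trophoblast median was 0.10 without KO library 06. Of the 2-cell-like list 4 genes were measured and none passed, in all genes or adjusted over the list alone, although 1 rose without KO library 04. The smallest p was that of Eif1a (0.12 ± 0.07, adjusted p = 0.206). Germline genes silenced by DNA methylation had 1 of 15 measured members up and 1 down, or 1 and 0 adjusted over the list alone (adjusted p = 0.816 in the upward direction, median -0.03, mean 0.01). The TFIID subunit paralog gene Taf7l rose (1.17 ± 0.17, adjusted p = 1.22e-07). The meiotic gene Tex11 fell (-0.76 ± 0.28, adjusted p = 0.0457), a call that ended in all fits without 1 library except that without WT library 03 (-0.44, adjusted p = 0.414 without WT library 02). Of 24 measured imprinted genes 4 rose and 4 fell, or 7 and 4 adjusted over the list alone (adjusted p = 0.658 in the upward direction, median 0.07, mean -0.03). Peg10 (-0.84 ± 0.05, adjusted p = 7.44e-25) and Mest (-0.46 ± 0.07, adjusted p = 8.1e-07), both on chromosome 6, fell. The adaptor protein gene Grb10 (0.31 ± 0.05, adjusted p = 2.47e-07) and Zdbf2 (0.41 ± 0.07, adjusted p = 8.75e-07) rose. The 5 measured Y-linked genes were detected in both groups, none passed, in all genes or adjusted over the list alone, and the list median was 0.06 (adjusted p = 0.758), with -0.03 without WT library 01, 0.02 without KO library 04, 0.09 without WT library 02, 0.10 without KO library 06 and 0.11 without WT library 03 or KO library 05. Ddx3y, an RNA helicase gene, had a log2 fold change of 0.24 ± 0.11 (adjusted p = 0.134), and among the 6 fits without 1 library it passed only without KO library 05 (0.33).

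Mitochondrially encoded transcripts rose in the KO, with 7 of 9 measured genes up and 0 down, also adjusted over the list alone (median 0.66, adjusted p = 1.85e-06, and adjusted p = 0.187 with an estimated correlation). The complex I subunit genes mt-Nd2 (0.85 ± 0.08, adjusted p = 1.84e-13), mt-Nd5 (0.59 ± 0.06, adjusted p = 3.54e-13) and mt-Nd6 (1.05 ± 0.13, adjusted p = 2.41e-10) and the cytochrome oxidase gene mt-Co1 (0.38 ± 0.05, adjusted p = 4.74e-10) led this list. Both mitochondrial ribosomal RNA genes were listed at 0 in every library, and mt-Co2, mt-Co3 and mt-Atp6 at 2 to 11 counts beside 2711 to 4829 for mt-Co1, so the list lacks usually abundant members. How such reads were assigned is not given in the sources used here. Immediate-early and heat shock genes, which respond to handling, did not pass as a list (median 0.04, adjusted p = 0.498; 0.02 without WT library 01 and 0.11 without WT library 03), with 3 of 13 measured members up and 2 down, or 5 and 2 adjusted over the list alone. The number that rose was 1 without WT library 01 or 02 or KO library 04. Btg2, an antiproliferative gene that is also in the p53 list, rose (0.98 ± 0.11, adjusted p = 6.55e-12), as did the AP-1 gene Jun (0.33 ± 0.11, adjusted p = 0.0216). The heme oxygenase gene Hmox1 (-0.35 ± 0.07, adjusted p = 2.1e-05) and the immediate-early gene Ier2 (-0.29 ± 0.06, adjusted p = 0.000536), both on chromosome 8, fell. The call of Jun ended without WT library 01 or 02 or KO library 04 or 06 (adjusted p up to 0.0772), and that of Ier2 with DESeq2 (0.124).

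**Figure D2:**
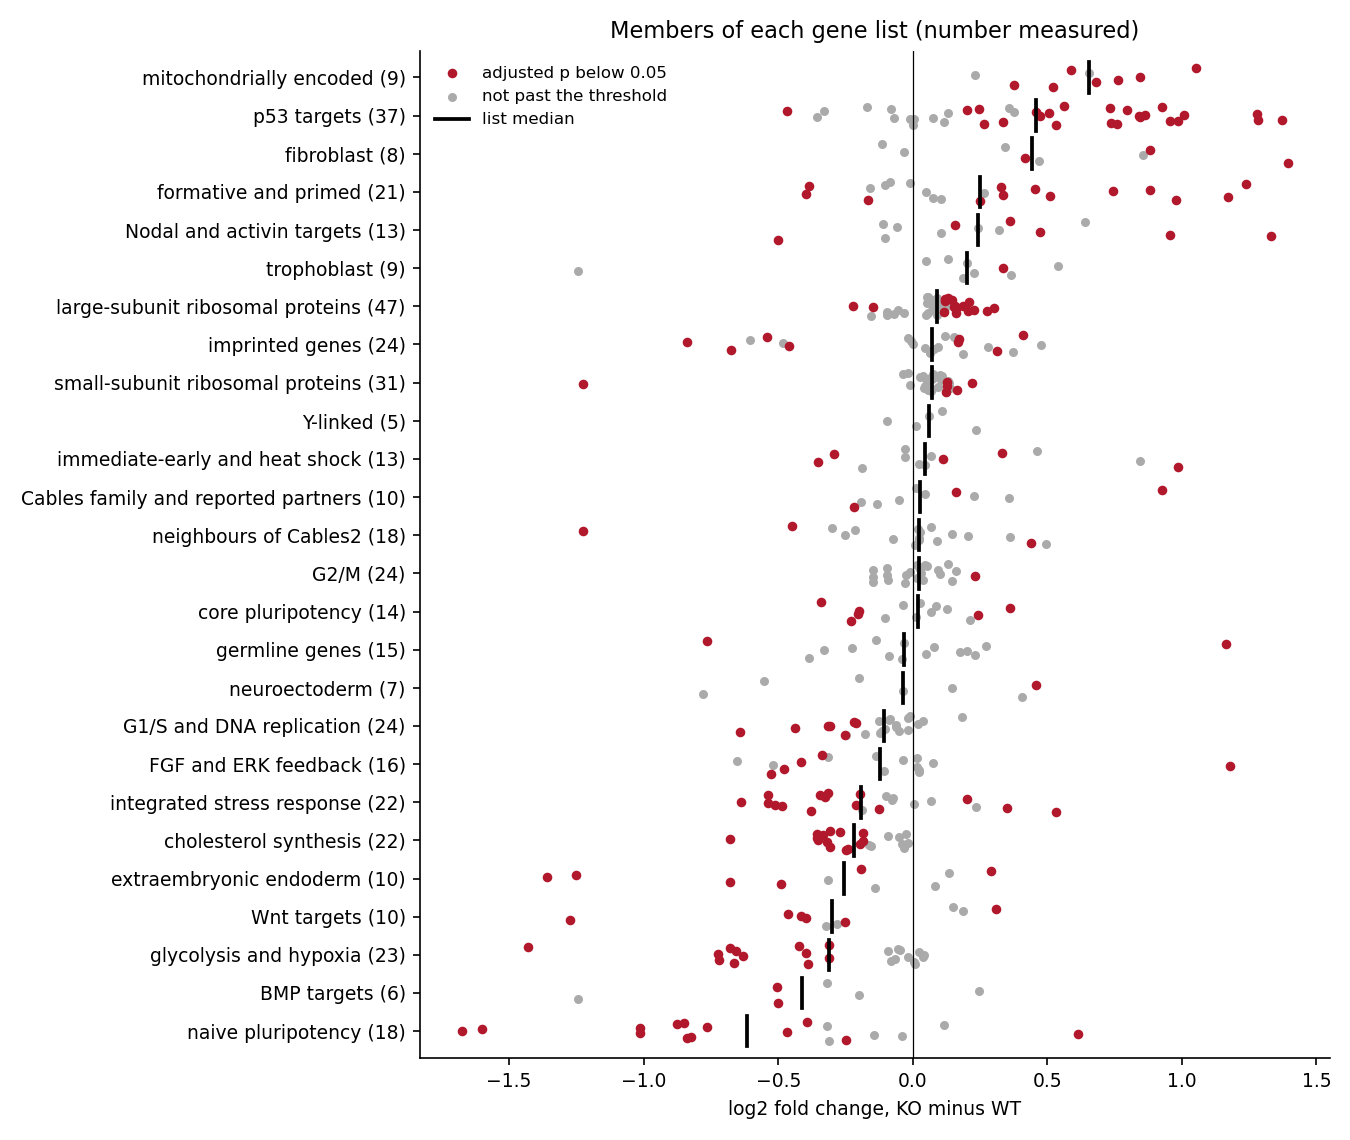
Log2 fold change (KO minus WT) of each measured member of the lists with at least 5 measured genes, 1 point per gene, with red points for an adjusted p under 0.05 and black bars for list medians. The p53 targets (median 0.46) and mitochondrially encoded genes (0.66) lie mostly to the right of 0, and naive pluripotency genes (-0.62) mostly to the left.

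The third comparison asked where in the genome the changed genes lie. Genes on chromosomes 6 and 8 were lower in the KO far more often than genes elsewhere. On chromosome 6, 192 of 537 tested genes fell and 6 rose (odds ratio of falling 6.54 against all other chromosomes, Fisher's exact test, adjusted p = 6.34e-68 over the chromosomes). On chromosome 8, 223 of 647 fell and 13 rose (odds ratio 6.36, adjusted p = 6.13e-76). Both p-values treat genes as independent, although all were measured in the same 6 libraries, so they do not measure the spread between libraries. An exact permutation test of 3 libraries against 3 cannot give a p below 0.1. The median log2 fold changes of chromosomes 6 and 8 were -0.25 and -0.21, against 0.03 for the genes of all other chromosomes. These 1184 genes, 10.2% of those tested, held 415 of the 1059 falls (39.2%). On the other chromosomes 924 genes rose and 644 fell. Refitted without the genes of chromosomes 6 and 8, the other genes gave 746 rises and 719 falls (50.9% higher), so the excess of rises depends on the fit. The refit changed the genes tested, the adjustment and the scaling factors together. The median log2 fold change of these other genes was 0.028 before and 0.0059 in the refit, so the scaling moved with it. The adjustment alone would move rises and falls in the same direction, whereas rises became fewer and falls more. How much each change contributed was not tested further. Relative to the summed counts of the autosomes other than 6 and 8, without Gm26917, chromosome 6 stood at 6.37% ± 0.00758 in WT and 5.13% ± 0.003 in KO. On the same scale chromosome 8 stood at 7.42% ± 0.00611 in WT and 6.37% ± 0.0519 in KO (SD, n = 3 each). In bins of 10 Mb with at least 20 tested genes, all 23 medians on chromosomes 6 and 8 lay between -0.37 and -0.15. On the other autosomes 2 of 173 such bins had a median below -0.1. Slc2a3, Peg10, Nanog and Ndnf on chromosome 6 had falls well beyond the chromosome's median.

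**Figure D3:**
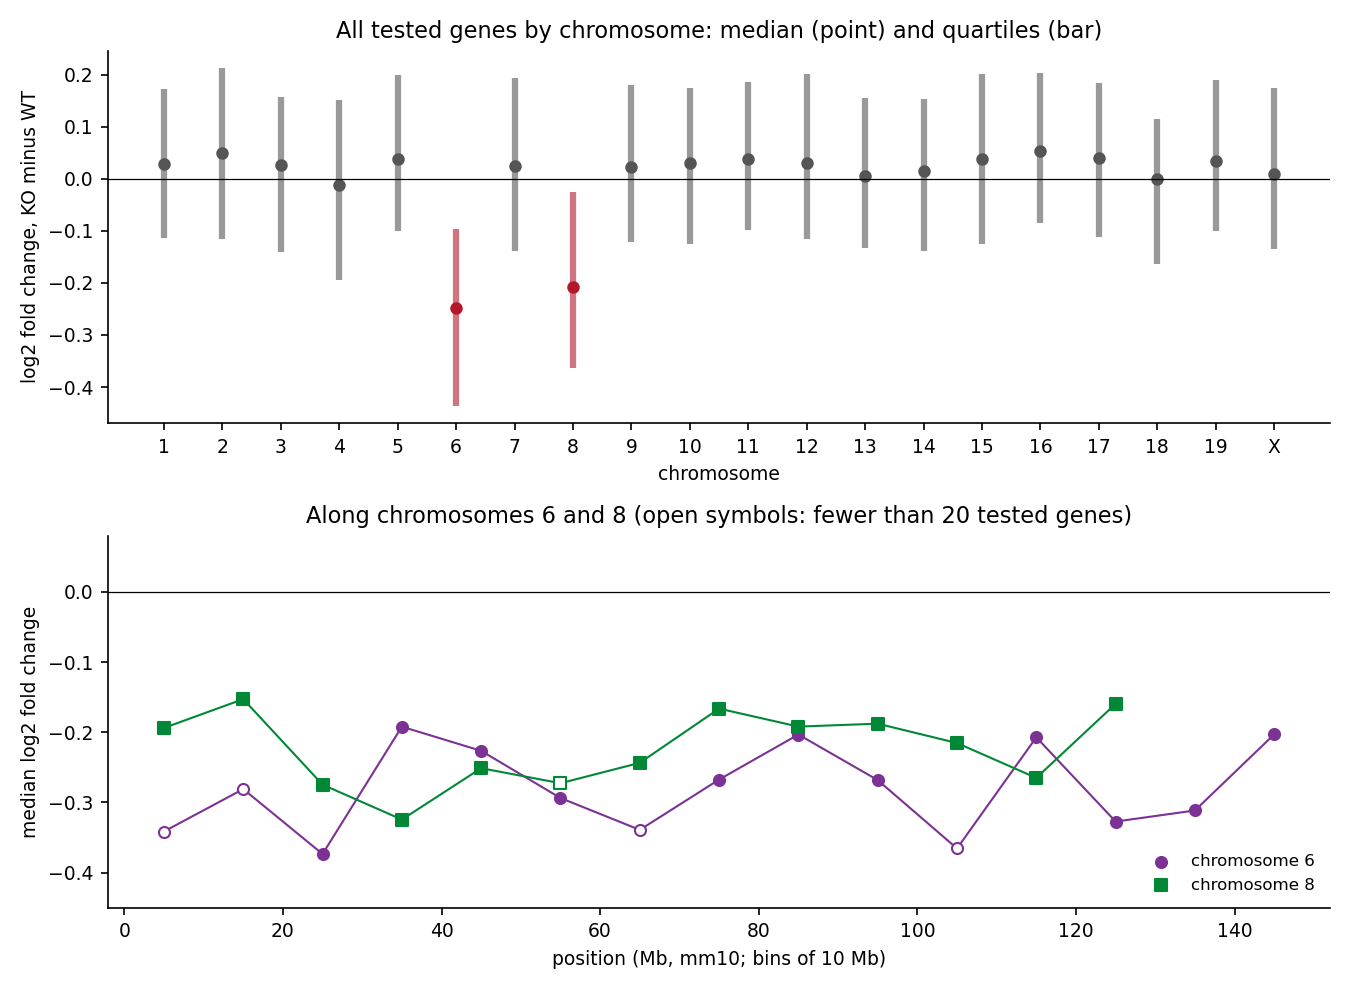
Top, median (point) and quartiles (bar) of the log2 fold change (KO minus WT) of the tested genes of each autosome and the X chromosome, with chromosomes 6 and 8 in red at -0.25 and -0.21. Bottom, medians of 10-Mb bins along chromosomes 6 and 8 in mm10, with open symbols for bins of fewer than 20 tested genes, all below 0.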

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

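Among the processing alternatives, the fits without genes of chromosomes 6 and 8, without the ribosomal RNA rows and with the GC and length trend removed were added after seeing the data. No paired analysis was possible because the count columns do not carry the replicate numbers of the labels. Of 101 named genes called, 84 passed in every alternative fit that gave a value (the stricter thresholds were applied to the gene totals alone), 86 passed in all 6 fits without 1 library, and 0 changed direction. DESeq2 gave no adjusted p for 8 named genes and ended 13 calls. Of the 15 lists called, 8 passed with camera in every alternative except the estimated correlation, and 10 in all fits without 1 library. The excess of falls on chromosomes 6 and 8 passed in all 15 alternatives, and Cables2 ranged from -4.59 to -3.96 without 1 library. Totals of called genes ran from 1566 to 1710 without 1 library, which leaves fewer samples. DESeq2 called 569 genes higher and 693 lower, all 1262 of them among the 2002 called by edgeR, and the cause was not tested. Stricter thresholds gave fewer by construction, 565 higher and 681 lower at an adjusted p under 0.01 and 105 higher and 44 lower at 2-fold or more. With the filter of CPM of at least 1 in 3 libraries, which tested 12706 genes, 4 lists were higher, and the cause was not tested. The count of higher lists was 4 to 6 without 1 library, with 4 without WT library 01. With the estimated correlation 0 lists were higher and 0 lower, and the cause was not tested further. A larger correlation between members cannot explain this for the naive pluripotency list. Its estimate of 0.0075 was below the preset 0.01, yet its unadjusted camera p went from 1.41e-08 to 0.00445. The same holds for the fibroblast list (estimate -0.0667, unadjusted camera p from 0.00734 to 0.0502). It also holds for G1/S and DNA replication (-0.00418, p from 0.000445 to 0.0176) and the integrated stress response (0.000113, p from 0.000749 to 0.0208). For FGF and ERK feedback the estimate was -0.0520 and the camera p went from 0.0155 to 0.0603. Estimates of the tested lists ran from -0.0667 (fibroblast) to 0.432 (mitochondrially encoded). Without genes of chromosomes 6 and 8 the sign changed for values near 0 that passed no test, Lama5 (-0.00088), Adrm1 (-0.013) and the medians of the G2/M (-0.00050), neuroectoderm (0.032) and germline (0.027) lists. That fit has other scaling factors and list members, and the cause was not tested further. Without 1 library, ranges that include 0 were -0.015 to 0.058 for Lama5, -0.052 to 0.061 for Adrm1, -0.021 to 0.071 for Rbbp8nl, -0.0012 to 0.031 for the core pluripotency list, -0.0036 to 0.043 for G2/M, -0.17 to 0.084 for neuroectoderm, -0.070 to 0.13 for germline and -0.029 to 0.11 for Y-linked genes, none of them called. Depth limits low genes, since 3 counts equal 0.576 to 0.708 CPM.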

Other observations

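The tests of the copy-number, minority-of-genes, segment, shared-read, ribosomal protein, deletion and chromosome 6 and 8 explanations, the splits of the libraries, and the gene families were chosen only after the results were seen, whereas both tests of GC content and exon length were set after the patterns were seen but before their own results.

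Families of genes that share a symbol root give values not described above. Of 54 tested histone genes, which encode mostly replication-dependent histones, 19 fell in the KO and 2 rose, with a median log2 fold change of -0.10. Hist1h2bb fell by 0.31 (SE 0.05, edgeR adjusted p = 2.69e-06) and Hist1h4j by 0.27 (SE 0.05, adjusted p = 4.25e-06), whereas Hist1h4a rose by 0.27 (SE 0.05, adjusted p = 3.55e-05). The family did not pass the list test over all families (camera adjusted p = 0.115, and adjusted p = 0.91 with an estimated correlation), although it did without the genes of chromosomes 6 and 8 (adjusted p = 0.011), which hold 1 of its members. Near-identical copies can share reads in this family, so single members are uncertain. Of 11 tested Srsf splicing factor genes 4 rose and 0 fell (median 0.08, adjusted p = 0.375), led by Srsf6 (0.44 ± 0.06, adjusted p = 2.16e-08) and Srsf2 (0.32 ± 0.06, adjusted p = 2.14e-05). Of 35 Trim ubiquitin ligase genes 6 rose and 0 fell (median 0.13, adjusted p = 0.115). None of the families passed after adjustment over all families.

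The falls on chromosomes 6 and 8 ran along the whole of both chromosomes. A bias of GC content or exon length is argued against by genes of other chromosomes matched on both, whose median log2 fold change was 0.031, and a fall of a minority of genes by the 81.3% of all tested genes on both chromosomes that lay below 0, against 44.9% elsewhere. A candidate explanation is a higher copy number of both chromosomes in part of the WT cells, or a lower one in KO cells, which would lower all bins, and the highest median of a 10-Mb bin with 20 or more genes was -0.15. The bins were known when this test was set, and any other cause that acts along whole chromosomes would lower them too, so the value does not single out copy number. With 3 copies against 2 in all cells the log2 fold change would be -0.58, which the medians relative to the other chromosomes (-0.28 and -0.24) did not reach, and which group carries the change and where it comes from stays open.

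The fall of Rps21 was weighed against 4 explanations. Loss of the surrounding segment is argued against by the median of 0.026 over the other 25 tested genes within 1 Mb, reads of the Cables2 transcript counted to Rps21 by a loss 8.80 times the whole WT level of Cables2, and a general fall of ribosomal protein transcripts by the median of 0.072 over the other small-subunit genes. The deletion may reach sequence that Rps21 needs, since 94 bases separate the annotated ends of both genes. These are the ends of transcription, and Rps21 starts on its side away from Cables2. The deleted interval is not given in the sources used here. An effect of the deletion on such sequence therefore cannot be told apart from an effect of Cables2 loss on Rps21. The KO libraries had 169.9, 171.0 and 169.1 CPM of Rps21.

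The rise of p53 targets kept a median of 0.46 after the trend on GC content and exon length was removed, a trend with an SD of only 0.014 over all genes, which argues against that trend as its cause. The median was 0.49 without the genes of chromosomes 6 and 8, but this decides nothing. The shift there is downward and all 23 members that rose lie on other chromosomes, so leaving its genes out was not likely to lower the median. A shortage of a ribosomal protein is known to activate p53, so the rise may follow from lower Rps21 as well as from the loss of Cables2 itself. These cannot be told apart here, because 0 libraries had lower Cables2 without lower Rps21. Indirect effects of the shift on chromosomes 6 and 8, the mitochondrial share and differences between ESC lines stay open as untested contributors.

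Other groupings of the libraries were also examined. The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. In each case 1 split, the real one, gave a result as large. The real split called 2002 genes by edgeR, and the highest of the others called 0, with 210 to 409 genes at an unadjusted p under 0.05 against 3408 for the real split. It called 15 lists against at most 5 in the others, and at most 223 genes in 1 direction on 1 chromosome against 0. The last 0 adds nothing, because the other splits called 0 genes in all. The absolute median log2 fold change of chromosome 6 was 0.248 in the real split and at most 0.107 in the others. For chromosome 8 it was 0.209 and at most 0.077. Each of the other splits puts WT and KO libraries together in both of its groups. A genotype difference then widens the spread within groups and shrinks the contrast between them. The smaller values of the other splits follow from this mixing, so they give no baseline for libraries without a genotype difference.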
